A study of Yarrowia lipolytica with 4 samples.

How the data were processed

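Total RNA of the dimorphic yeast Yarrowia lipolytica, grown on a synthetic agar medium without thiamin (TH-) or with thiamin (TH+), was compared on 4 custom Agilent arrays with 2 colours. Each array paired the RNA of 1 TH- culture with that of 1 TH+ culture, and the labels describe the 4 pairs as biological replicates. TH- RNA carried Cy3 in replicates 1 and 3 and Cy5 in replicates 2 and 4, so that a dye effect of equal size on all arrays cancels in the mean. The series text puts the RNA at day 8, whereas the growth protocol gives 14 days of culture at 25 °C. Per the labels' protocols, TH+ RNA was extracted with Trizol and TH- RNA with RNeasy columns, so that growth condition and extraction method cannot be told apart in any ratio given here. All 4 arrays lay on 1 slide.

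The deposited scanner files give the intensity of each spot and of its surround in both dyes on a linear scale, made with Agilent Feature Extraction 10.7.3.1, per the file headers. They also hold a log10 ratio of Cy5 over Cy3 that Feature Extraction computed after background subtraction and dye normalization, per the file headers. Each array has 14858 spots, of which 536 are controls, 12882 are exonic probes of Y. lipolytica loci, 1411 are intronic probes and 29 are probes for 9 transgenes or foreign genes. The deposited value table is on a log2 scale but holds no ratio per spot. Each of its columns is a smooth curve of the array's average log intensity (at least 99.9% of the variance over spots in each column), with medians of -1.33, 1.33, -0.02 and 1.46 for replicates 1 to 4. Its sign follows TH- over TH+, and how the authors computed it is not given in the sources used here. It could not serve as a table of gene ratios. The genome build behind the probe coordinates is not given in the sources used here, so coordinates are those of the array design.

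The mean spot signal was corrected for the median local background with normexp (offset 50), and log ratios were normalized within each array by loess, with control spots at weight 0 (limma 3.58.1, R 4.3.3). Spots with an outlier flag were left out; 1 spot outside the controls had such a flag on the 4 arrays together, and no spot was saturated. An exonic probe was kept where it was well above background in the channel of 1 condition on at least 3 of the 4 arrays. This left 11741 probes of 6260 loci and removed 276 loci. On replicate 1 all 29 transgene and foreign gene probes were well above background in both channels. On each other array, 12 to 18 of the 29 were so in a channel. Being well above background therefore does not establish that a gene was expressed. Ratios were turned to log2(TH-/TH+), and the probes of a locus were averaged. Of the loci called, 3119 had over 1 probe, and the probes of 68 differed in sign. The log2 ratio of each locus was tested against 0 with lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05. Loess sets the average ratio at each intensity to about 0, so that higher and lower mean relative to the average gene of comparable intensity. For arrays, the number of replicates limits the precision. On simulated ratios of the same 6260 loci with the observed spread, the procedure recovered 89.6% of the loci changed 1.5-fold, and 100% of those changed 2-fold or 4-fold, and 3.5% of its calls were false. Only 67, 67 and 66 loci were changed 1.5-fold, 2-fold and 4-fold, with independent noise of the same size on all 4 arrays. In the data many more loci were called and the arrays were not equally alike, so these shares need not hold there.

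Neither the files nor the reference table, which describes another assembly and matched 0 of the array's 6539 loci, pairs these loci with gene names. The names used below are published Y. lipolytica gene names attached to 45 locus tags in a list written from general knowledge before the data were examined, and they are not assigned by the files. As a check, translated exonic probes of all 6536 loci were aligned to S. cerevisiae protein sequences, also recalled rather than taken from a database (Biopython 1.88). The loci listed as THI4, LEU2 and GPD1 each ranked 1 of 6536. The locus listed as MHY1 ranked 167 against a recalled zinc finger stretch (alignment score 29, against 55 for the best other locus), so that the check did not support that name; whether its probes lie in the zinc finger is not known here, and the other names were not tested in this way. The rule fixed before the data were examined named the 8 most raised and the 8 most lowered loci that the files name, the leading members of each gene list called, every measured thiamin gene and the called regulators of hyphal growth. Since the files name no locus and camera, the test that defined a called list, called none, only its last part gave names, and the called loci of the whole tag list were added after the values were seen. The 28 gene lists fixed in advance had tagged loci in 9 lists, and 4 lists with at least 3 measured loci were tested with camera (preset correlation 0.01, then an estimated correlation) and fry. No conclusion can be drawn on the 19 lists without a tagged locus.

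The alternatives tried were other background corrections, Agilent's own ratio, median centring, other normalizations between arrays, looser and stricter filters on dim probes, a dye term, a trended and robust prior, array weights, the brightest probe per locus, a separate-channel fit, removal of a trend on probe GC content and leaving out each replicate in turn. Centring on spike-in RNAs, subtraction of the deposited intensity curve and averaging replicates 2 and 4 were added after seeing the data.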

Results

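The study asked how thiamin affects the morphology of Y. lipolytica, a yeast that grows either as single cells or as hyphae. Transcript levels were compared between cultures grown without thiamin (TH-) and cultures grown with it (TH+), as 4 ratios from 4 pairs of biological replicates. In replicates 2 to 4, between 82.5% and 92.1% of the probes outside the controls were well above background in either channel. In replicate 1 these shares were 98.5% for TH- and 99.0% for TH+, and its 29 probes for transgenes and foreign genes had a median signal of 447, against 57.0 to 73.2 on the other arrays. Across the 6260 loci tested, the log ratios of replicate 1 correlated with those of the other arrays at r = 0.83 to 0.85, and those of the other arrays with each other at r = 0.94 to 0.98. These correlations are across genes, which are not independent replicates. The 2 conditions also differed in RNA extraction method, which applies to every ratio below.

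Without thiamin, the locus with the highest ratio of all 6260 tested was YALI0A09768g, listed as THI4, which encodes the enzyme that makes the thiazole part of thiamin. Its transcript was 62.0-fold higher in TH- than in TH+, with a log2 ratio of 5.95 ± 0.71 (SD, n = 4) and an adjusted p of 6.6e-06 in the limma fit. Its 2 exonic probes lie on chromosome A between positions 979399 and 979498 of the array design, and it was higher on 4 of 4 arrays. Median centring without loess gave a log2 ratio of 6.74. It was the only measured member of the fixed list on thiamin synthesis, uptake and phosphorylation. LEU2 (YALI0C00407g), a leucine synthesis gene and the only measured member of its list, had a log2 ratio of 0.01 ± 0.15 (SD, n = 4; adjusted p = 0.94).

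Both measured loci listed as regulators of the switch from yeast to hyphal growth had lower transcript levels without thiamin. The locus listed as MHY1 (YALI0B21582g, chromosome B, probes between 2836749 and 2836898) was 8.32-fold lower in TH-, with a log2 ratio of -3.06 ± 0.27 (SD, n = 4; adjusted p = 5.1e-06). MHY1 is known as a zinc finger transcription factor gene needed for hyphal growth, but the sequence check did not support this name for the locus (rank 167 of 6536). HOY1 (YALI0A18469g, chromosome A, probes between 1966025 and 1967424), a homeobox gene also needed for hyphae, was 4.95-fold lower, with a log2 ratio of -2.31 ± 0.16 (SD, n = 4; adjusted p = 6.2e-06). Both were lower on 4 of 4 arrays. MHY1 was 5.48-fold lower with median centring without loess, and HOY1 was 7.81-fold lower on its brightest probe alone. By ratio they ranked 27 and 78 from the lowest of the 6260 loci. With only 2 measured members, this list was not given a set test.

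The alkane hydroxylase cytochromes P450, which start the breakdown of alkanes, moved in both directions. Of the 11 measured ALK genes, 6 were higher in TH-, 2 were lower and 3 did not pass the test. Adjusted over the list alone, 9 passed, 7 of them higher. The gene added was ALK11 (log2 ratio 0.31 ± 0.27, SD, n = 4). In TH+ it was well above background on only 1 of 4 arrays, and its ratio in replicate 1 was -0.096. ALK2 (YALI0F01320g, chromosome F, probes between 211944 and 212143) was 12.6-fold higher, with a log2 ratio of 3.65 ± 0.53 (SD, n = 4; adjusted p = 1.7e-05). ALK7 was 2.81-fold, ALK4 1.99-fold, ALK6 1.91-fold and ALK1 1.57-fold higher. The sizes of the larger increases depended on the background correction, and with Agilent's processed ratio ALK2, ALK7 and ALK4 were 31.8-fold, 8.66-fold and 3.79-fold higher. In TH+, ALK7 was well above background on 3 arrays. ALK12 passed the test as higher but was well above background in TH+ on only 1 of 4 arrays, so that its size is poorly measured, with log2 ratios of 0.43 here and 2.23 with Agilent's processed ratio. The call on ALK12 was lost without the filter on dim probes (log2 ratio 0.24, adjusted p = 0.0713) and with median centring without loess (0.14, adjusted p = 0.65). It was also lost without replicate 3 (log2 ratio 0.34, adjusted p = 0.0606) or without replicate 4 (adjusted p = 0.0717). ALK3 was 2.53-fold lower, with a log2 ratio of -1.34 ± 0.59, and ALK5 was 1.72-fold lower, with a log2 ratio of -0.78 ± 0.42 (SD, n = 4); centred on spike-in RNAs, ALK5 changed sign and the call on ALK3 was lost. The mean log2 ratio of the list was 0.55, and limma's camera test detected no shift against all other genes (adjusted p = 0.44).

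Genes of peroxisomal fatty acid oxidation were also split, with 3 of 7 measured members higher, 3 lower and 1 not past the test. Adjusted over the list alone, 6 passed as well. POX2, an acyl-CoA oxidase gene, was 2.29-fold higher (log2 ratio 1.19 ± 0.15), POT1, the thiolase gene, was 2.34-fold higher (log2 ratio 1.23 ± 0.40), and MFE2, the multifunctional enzyme gene, was 1.44-fold higher (log2 ratio 0.52 ± 0.17; SD, n = 4). In contrast, the acyl-CoA oxidase genes POX5, POX4 and POX6 were 2.22-fold, 1.43-fold and 1.34-fold lower, and when centred on spike-in RNAs the call on POX5 was lost and the ratios of POX4 and POX6 changed sign. Median centring without loess also ended the calls on POX5 (log2 ratio -0.64, adjusted p = 0.052) and POX6 (log2 ratio -0.27, adjusted p = 0.14). The mean log2 ratio of the list was 0.14, with no shift detected by limma's camera test (adjusted p = 0.94). ICL1 (YALI0C16885g), the isocitrate lyase gene of the glyoxylate cycle, was 1.94-fold higher, with a log2 ratio of 0.96 ± 0.36 (SD, n = 4; adjusted p = 0.0013), and 3.26-fold higher with median centring without loess.

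In the list on fatty acid and storage lipid synthesis, 2 of 14 measured members were higher, 6 were lower and 6 did not pass the test, with 8 passing when adjusted over the list alone. Of the measured acyltransferase genes of neutral lipid synthesis, 1 was lower, 2 were higher and DGA2, the other diacylglycerol acyltransferase gene, did not pass the test (log2 ratio -0.06 ± 0.54, SD, n = 4; adjusted p = 0.81). DGA1 (YALI0E32769g, chromosome E, probes between 3887307 and 3888356), a diacylglycerol acyltransferase gene, was 4.05-fold lower in TH- (log2 ratio -2.02 ± 0.33; adjusted p = 4.7e-05), whereas ARE1 (YALI0F06578g, chromosome F, probes between 975307 and 975956), an acyl-CoA:sterol acyltransferase gene, was 3.96-fold higher (log2 ratio 1.99 ± 0.19; adjusted p = 1.3e-05; SD, n = 4). On the same arrays the ratio of ARE1 exceeded that of DGA1 by 4.00 ± 0.52 log2 units (SD, n = 4), a difference that a shift common to all genes does not touch. ARE1 was 7.21-fold higher with Agilent's processed ratio. LRO1, another acyltransferase gene, was 1.86-fold higher. The desaturase genes OLE1 and FAD2 were 1.74-fold and 1.64-fold lower, and GPD1, the glycerol 3-phosphate dehydrogenase gene, was 1.43-fold lower. TGL3 and TGL4, which belong to lipid breakdown rather than synthesis, were 1.24-fold and 1.29-fold lower. These 5 smaller decreases changed sign when centred on spike-in RNAs, and GPD1 also with median centring without loess. The latter setting ended the calls on OLE1 (log2 ratio -0.066, adjusted p = 0.83), FAD2 (-0.16, adjusted p = 0.52) and TGL3 (-0.13, adjusted p = 0.48). The 2 probes of TGL3 differed in sign, and its call was also lost with normexp at offset 0 (adjusted p = 0.095) and with Agilent's processed ratio (adjusted p = 0.13). The calls on TGL3 and TGL4 were lost without replicate 2 (adjusted p = 0.0941 and 0.0635), replicate 3 (0.0635 and 0.0781) or replicate 4 (0.0962 and 0.0969), although their log2 ratios stayed between -0.30 and -0.29 for TGL3 and between -0.39 and -0.31 for TGL4. The mean log2 ratio of the list was -0.15, and limma's camera test did not call it (adjusted p = 0.44).

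Among the secreted proteases and lipases, 1 of 4 measured members was higher, 2 were lower and 1 did not pass the test, with 3 passing when adjusted over the list alone. XPR2 (YALI0F31889g), the alkaline extracellular protease gene, was 3.47-fold lower in TH- (log2 ratio -1.80 ± 0.75; adjusted p = 0.0013). AXP1 (YALI0B05654g), the acid extracellular protease gene, was 1.95-fold higher (log2 ratio 0.96 ± 0.26; adjusted p = 5.6e-04; SD, n = 4). The size of these changes depended on the background correction. XPR2 was 7.55-fold lower with normexp at offset 0 and 11.4-fold lower with Agilent's processed ratio, with which AXP1 was 3.67-fold higher. The lipase gene LIP8 was 3.19-fold lower (log2 ratio -1.67 ± 0.60, SD, n = 4). Their mean log2 ratio was -0.59, which limma's camera test did not call (adjusted p = 0.80), so that 0 of 4 lists were called and 0 also at an unadjusted p under 0.05. With an estimated correlation, the adjusted p was 0.94 for peroxisomal oxidation and 0.84 for each of the other 3 lists. The fry test sets members against 0 and not against other genes. By fry, members of each of the 4 lists changed in either direction (adjusted mixed p of at most 0.0091). Since 56.2% of all loci were called, a small mixed p says little about these lists in particular. The ALK genes moved on balance upward from 0 by fry (adjusted p = 0.034), while the adjusted p of the other 3 lists was 0.13. Whether the lists differed from each other was not tested. AOX1, the alternative oxidase gene, was 1.49-fold lower (log2 ratio -0.58 ± 0.29, SD, n = 4), and changed sign both with median centring and when centred on spike-in RNAs.

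**Figure D1:**
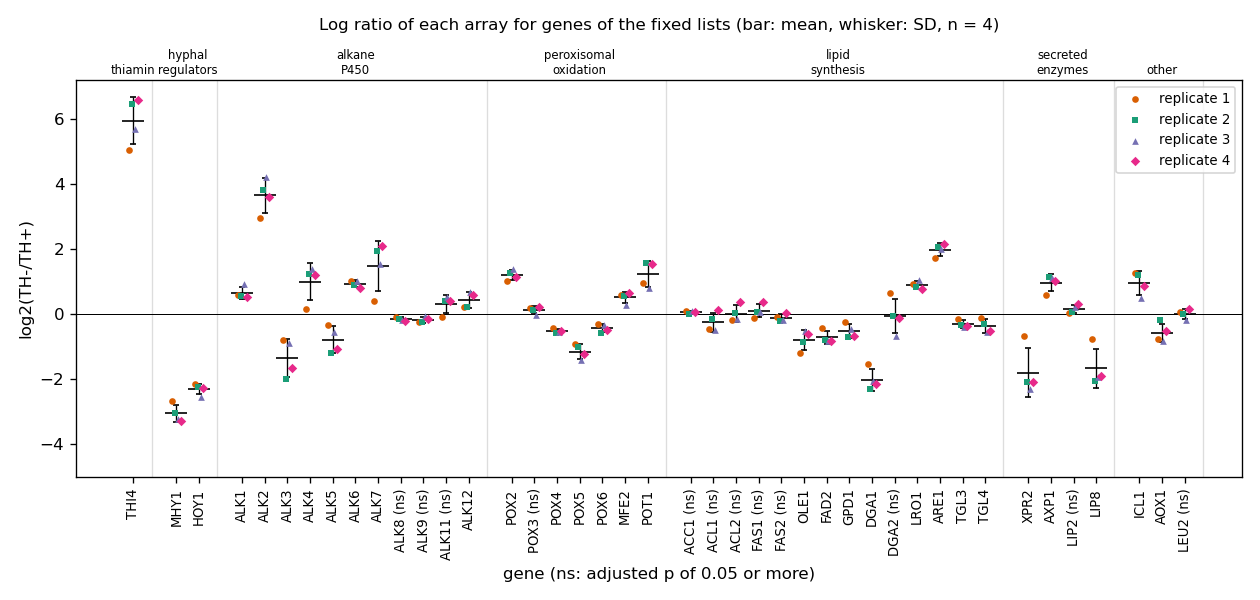
Log2(TH-/TH+) of each gene on the vertical axis, 1 point per array, with the mean as a bar and the SD as a whisker (n = 4), for the tested genes of the fixed lists. THI4 has the highest mean at 5.95 and MHY1 the lowest at -3.06, and ns marks genes with an adjusted p of 0.05 or more.

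Over the whole array, 3515 of 6260 loci (56.2%) differed between the conditions at an adjusted p under 0.05, of which 1915 were higher and 1600 lower in TH-. At least 2-fold differences were found for 874 loci, 391 higher and 483 lower (1490 loci with Agilent's processed ratio), and at least 4-fold differences for 97 higher and 117 lower loci. Of the loci called, 3433 had the same sign on all 4 arrays. Of the 8 most raised loci 7 had no name here, and of the 8 most lowered loci 8 had none. YALI0F19492g and YALI0E34441g were 20.04-fold and 19.9-fold higher in TH-, whereas YALI0A03421g and YALI0F22011g were 32.7-fold and 25.2-fold lower. No locus was called for a dye effect in the limma fit with a dye term (0 of 6260), but 659 had an unadjusted p under 0.05, against 313 by chance. A dye effect of equal size on all arrays cancels in the mean over 2 arrays of each orientation. In dim loci, where replicate 1 had smaller ratios, it may cancel only in part. The split into higher and lower loci depended on the normalization. Median centring without loess gave 1835 higher and 941 lower loci. Centring on the spike-in RNAs, chosen after seeing the data, moved the median log2 ratio of all loci from 0.06 to 1.19 and gave 5652 higher and 242 lower loci, so that the directions above hold relative to the average gene.

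**Figure D2:**
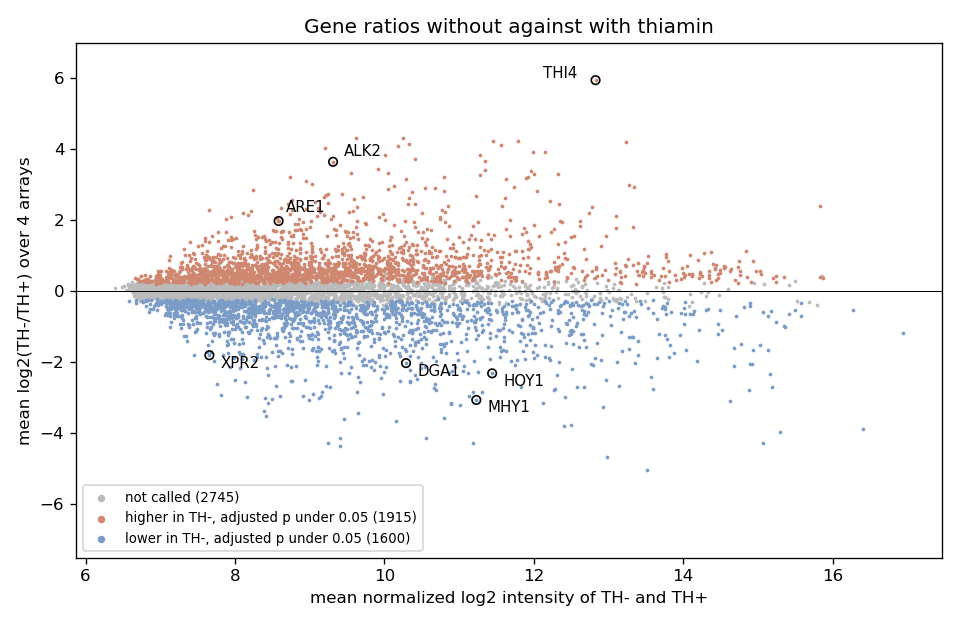
Mean log2(TH-/TH+) over the 4 arrays (vertical axis) against the mean normalized log2 intensity of both conditions (horizontal axis), 1 point per locus for 6260 loci, coloured by the call at an adjusted p under 0.05. The 1915 higher and 1600 lower loci span the range of intensity, and THI4 lies above all other loci at 5.95.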

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

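All tests of explanations in this part were chosen after the result was seen. Across 49 sets of 4 array values examined, 7 had a replicate far from the others, 6 of them replicate 1, where chance alone marks about 1 in 20. The distant values were the log2 ratios of ALK4 (0.15), FAD2 (-0.43), LIP8 (-0.77) and XPR2 (-0.68) in replicate 1, each closer to 0 than on the other arrays, and that of ALK1 in replicate 3 (0.91). In replicate 1 the median signal of the transgene probes (447) and of the TH+ channel (1326) were also far above the other arrays.

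The smaller ratios of replicate 1 followed signal strength. Its slope on the mean of the other arrays was 0.40 in the dimmest quartile of loci and 0.90 in the brightest. In the middle quartiles it was 0.52 and 0.66. The slopes of the other arrays lay between 1.00 and 1.21, but the mean each was set against includes replicate 1. Smaller ratios in replicate 1 raise those slopes by construction, so they are not a separate contrast. The correlation of 0.86 across genes with the mean of the other arrays argues against swapped dyes or a wrong label. Signal on probes without an expected target, together with the slope of 0.40, is consistent with a raised non-specific signal that compressed the ratios of dim genes. A culture that differed from the others could still account for part of it, and no biological explanation was tested.

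Probes for 10 spike-in RNAs, with 20 spots each, were not used in the comparisons. Their log2(TH-/TH+), averaged over both dye orientations so that the composition of the mixes cancels, was -1.13 ± 0.30 against the genes (SD over 10 spike-in RNAs), below 0 for 10 of 10. Gene signal per spike-in signal was thus 2.19-fold higher in TH-, a size that depended on the normalization, since median centring without loess gave a log2 shift of -0.56. The background of replicate 1 does not account for it, since replicates 2, 3 and 4 alone gave -1.21. Nor does compression of dim spots, since the 5 brightest spike-in RNAs gave -1.31 and the 5 dimmest a smaller shift of -0.96. A different share or quality of mRNA in the RNeasy extracts (TH-) and the Trizol extracts (TH+) is a candidate explanation that cannot be told apart from growth condition, because 0 of the 4 arrays separate them, and unequal amounts of RNA or spike-in mix also stay open.

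The 1411 intronic probes were likewise outside the comparisons. Leaving out replicate 1, 74.8% of their readings were well above background, against 51.1% for the transgene probes. In 604 loci measured in both parts, the intronic log2(TH-/TH+) lay below the exonic one by a median of -0.31, and the 4 arrays gave -0.31, -0.30, -0.37 and -0.37. The size depended on the processing, with -0.58 for normexp at offset 0, -0.72 for Agilent's processed ratio and -1.01 for median centring without loess. In the limma fit of this difference, 275 loci were lower and 64 higher at an adjusted p under 0.05. Of the 5 named genes measured in both parts, the difference was called lower for ICL1 (-1.02), ACC1 (-0.53) and FAS1 (-0.37). FAS2 (-0.30, adjusted p = 0.073) and GPD1 (0.11, adjusted p = 0.51) did not pass the test. For ICL1 the intronic log2 ratio was -0.06 and the exonic one 0.96, so the difference lay mostly in the exonic rise. The exonic value of ACC1 rests on 1 dim probe, well above background on 3 of 4 arrays in each condition.

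Intronic probes lay -0.35 from exonic probes of matched brightness, which argues against a trend with brightness left by the normalization. Such a trend would move both kinds of probe alike. Matching on brightness cannot decide on genomic DNA in the TH+ extracts, since DNA may give a larger share of the signal of intronic probes. Without replicate 1 the intron minus exon median was -0.34, so that the background of that array is not the cause. A smaller share of unspliced RNA without thiamin, a different recovery of it by the extraction methods, or genomic DNA in the TH+ extracts may remain. The design does not separate these. Non-specific signal was not excluded either. Leaving out replicate 1, 51.1% of the transgene readings were also well above background. The intronic probes kept were dimmer than the exonic ones (median log2 intensity 7.38 against 8.72). The ratio of the transgene probes was not compared with theirs.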

How the results depend on the processing

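The alternatives of spike-in centring, the deposited intensity curve and averaging replicates 2 and 4 were chosen after seeing the data; the others were fixed before the data were examined. Leaving out 1 replicate in turn gave between 2635 and 4122 differing loci, the most without replicate 1, whose array weight was 0.21. Replicates 2 and 4, both with TH- in Cy5, were closer to each other than other pairs (r = 0.98 across genes, SD of the difference 0.16, against 0.32 to 0.48). For replicates 1 and 3, both with TH- in Cy3, this SD was 0.48. Whether the shared orientation accounts for the closeness was not tested. The labels describe replicates 2 and 4 as separate biological replicates, and the ratios cannot tell how independent they are. If they are not independent, the p-values from 4 replicates may be too small. Averaging replicates 2 and 4 as 1 replicate gave 2732 differing loci. It ended the calls on TGL3 (log2 ratio -0.30, adjusted p = 0.090) and TGL4 (-0.36, adjusted p = 0.073). Their ratios stayed close to those from 4 replicates. Of the 30 named genes that passed the test, 17 kept their direction and their call under all 21 settings run, and ALK7 under the 20 in which it was tested. Median centring without loess gave 941 lower loci, reversed the sign of GPD1 (log2 ratio 0.026) and AOX1 (0.51), and ended the calls on POX5, POX6, ALK12, OLE1, FAD2 and TGL3. Agilent's processed ratio gave 1490 loci with at least 2-fold differences. The direction of the peroxisomal list against other genes reversed with normexp at offset 0 (mean log2 ratio 0.13), with Agilent's ratio (0.11) and without the filter on dim probes (0.11), with no call in any of them. The cause was not tested. Centring on the spike-in RNAs shifts every locus by the same amount, and by that construction gave 5894 differing loci, 5652 higher, 242 lower and 4216 at least 2-fold. Limma's camera test then called secreted proteases and lipases downward against other genes (mean log2 ratio 0.55, median of all loci 1.19, adjusted p = 0.046). A constant shift leaves the distance of a list from other genes in log ratio unchanged. The call, absent from camera in the main setting (adjusted p = 0.80), therefore adds no support for a shift of this list. Spike-in centring reversed the sign of POX4 (0.62), POX6 (0.71), ALK5 (0.35), OLE1 (0.34) and FAD2 (0.42). The signs of GPD1 (0.61), TGL3 (0.82), TGL4 (0.76) and AOX1 (0.56) were reversed as well. THI4, ALK2, ARE1, MHY1, HOY1, DGA1, XPR2 and LIP8 kept direction and call under every setting run.

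The quantile normalization of intensities leaves ratios untouched and tests nothing here. The slide as a block was not run, since all arrays share 1 slide. The deposited value table as gene ratios, a trend on coding length and lists without the tag list were not run, because the table holds no ratios, no lengths match these loci and no list members would be left. The main test is already paired, since the ratio of each array sets a TH- sample against its TH+ partner. No further pairing was possible, because all arrays form 1 group. Signal over background limits what the dim loci show, and in replicate 1 the raised signal of probes without an expected target does so.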

Other observations

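All tests in this part were chosen after the result was seen. Loci next to each other on a chromosome had similar ratios slightly more often than in shuffled gene orders, with a correlation across neighbouring loci of 0.06 against at most 0.04 in 1000 shuffles within chromosomes (permutation p = 0.001, the smallest they can give). The lowest run of 5 neighbouring loci lay on chromosome B between positions 2863031 and 2873556 of the array design. Its 5 loci were all called lower in TH-, with log2 ratios from -3.80 to -0.48 and a mean of -2.22, and 12 of 1000 shuffles gave a run as low (permutation p = 0.013). The highest run, on chromosome A between 2146012 and 2153380, had a mean of 1.96 (permutation p = 0.085). Within 20 kb of the outermost probe of a chromosome, 19 of 80 loci (23.8%) were changed at least 2-fold, 8 higher and 11 lower, against 13.8% of the other 6180 (Fisher's exact test, two-sided, p = 0.021). Over these 4 tests of position, the Benjamini-Hochberg adjusted values were 0.004, 0.026, 0.085 and 0.028. Fisher's test treats loci as independent, although neighbouring loci had similar ratios here, so its p and the adjusted 0.028 may be too small. These results suggest that part of the response may be grouped by position; shared probes of gene copies were not examined.

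On the same arrays, the ratio of the acid protease gene AXP1 exceeded that of the alkaline protease gene XPR2 by 2.76 ± 1.00 log2 units (SD, n = 4), from 1.27 in the array with the smallest difference to 3.42, above 0 on 4 of 4 arrays. In Y. lipolytica these genes are known to respond to ambient pH in opposite ways. A hypothesis is that the medium without thiamin may have been more acid at sampling. The difference of 2.76 is the observation that raised the hypothesis and cannot decide it, and no pH is given in the sources used here.

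The 4 ratios can be turned in 8 ways, counting a pattern and its mirror once. The real orientation gave 3515 differing loci and the highest of the others gave 0. Thus 1 of 8 ways gave as many, and 8 are too few for a share under 0.05. Turning an array also moves the differences that all 4 arrays share into the spread between arrays. Few calls in the other ways were therefore set in advance, and 3515 against 0 cannot decide on chance.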
